A study of Homo sapiens with 21 samples.

How the data were processed

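The data are gene-level read counts from sequencing of poly(A) RNA. Per the labels' protocols, cells were plated with or without IFN-α2a the day before 3p-RNA was transfected with a lipid reagent. Total RNA was extracted, freed of DNA and enriched for poly(A) RNA, and libraries were made with a directional kit, again per the labels' protocols. The deposited table gives raw counts, 1 column per library, which the authors did not normalise as far as the values show (all are whole numbers). Per the submitters' processing notes, BWA, featureCounts and Subread 1.4.6-p3 were used on genome build GRCh38. The name of the deposited table states annotation release Ensembl 85. The strand setting of the counting, the read length and the handling of reads that map to several places are not given in the sources used here. Genes that overlap, that lie antisense to one another or that have near-identical copies are therefore uncertain.

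The table holds 58051 genes, of which 22445 had 0 counts in every library. GENCODE release 29 (Ensembl 94) gave symbols, biotypes and coordinates, matching 57447 of the identifiers. The 604 unmatched ones held at most 0.0230% of the counts of any library. Total counts per library ran from 11822568 to 24808344. No pair of libraries within a group was alike within sampling noise.

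All 21 libraries entered 1 edgeR model with a mean per group, so that all groups share an estimate of spread with 14 residual degrees of freedom. Counts were scaled with TMM factors, genes were kept with filterByExpr (16044 kept, 12662 of them protein-coding, 42007 dropped), and the quasi-likelihood test was run for 9 comparisons. The p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene counts as called at an adjusted p under 0.05. The common dispersion was 0.00733, a biological coefficient of variation of 8.56%. CPM values are on TMM-scaled library sizes. The programs were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Python 3.11.15.

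The 26 gene lists were written from general knowledge before the data were examined, and every listed symbol was matched to an identifier. The 22 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, beside camera with estimated correlation and fry, adjusted over the lists within a comparison. Sensor genes, interferon-stimulated genes and some other lists share members. Medians are given over tested members. At-bound medians set a group without counts to 3 counts per library.

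The genes named per comparison were fixed by rule before the data were examined. They are up to 6 called protein-coding genes with the largest rise and up to 6 with the largest fall, with a mean of at least 5 CPM in the higher group. Comparisons of 2 groups also asked for no overlap between the libraries of both groups. The interactions did not, and there the 5 CPM were asked of the highest group involved. DDX58, OAS1, OAS2, OAS3, IFNB1, PMAIP1, MCL1 and BCL2L1 are always named; some further genes are not reported here. From each list described, up to 3 called members with the smallest p are named, or the 2 most abundant where none was called. "At least" folds are given where a group has 0 counts, and ratios with a 95% counting interval where it has 1 to 3.

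Alternatives chosen before the data were examined were RLE factors, library size only, no filter on low counts, at least 5 CPM in 3 libraries (12063 genes), limma-voom, DESeq2, a fit of the compared groups only, each library left out in turn, a 2-fold threshold and a term for replicate number. Chosen after the data were examined were thinning of every library to 11822568 counts, a per-library correction on GC content and transcript length (15997 of the tested genes, 99.7%, have values) and a closer look at the fit without KO untreated replicate 2. Lists of NRF2 targets and of nuclear-retained RNAs, and the grouping of genes by RNA class, were also written after values had been seen.

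The model and the set test were tested on simulated data drawn from the real means, dispersions and library sizes, with 200 of 16044 genes changed. This test was run after the main fit. Of 100 genes changed 2-fold, 96 were recovered for WT 3p-RNA, 100 for KO 3p-RNA, 91 for the genotype interaction, 97 for KO against WT, 97 for IFN at 4 h, 94 for IFN at 18 h, 97 for 18 h against 4 h, 99 for 3p-RNA after IFN and 93 for the IFN interaction. Of 100 genes changed 1.5-fold, 87, 77, 62, 85, 83, 79, 79, 91 and 58 were recovered in the same order. False calls made up 1.62% to 7.93% of the calls. For KO 3p-RNA, the only comparison in which this was run, none of 50 random gene sets was called by camera. The simulated genes were drawn independently of one another. The simulation therefore does not show how camera at the preset correlation behaves where genes are correlated.

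Reads, transcript isoforms, editing at the DDX58 site and RNA integrity were not analysed here. No library was left out.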

Results

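Poly(A)-enriched RNA of 1205Lu cells, a human melanoma line, was sequenced from wild-type (WT) cells and from cells whose RIG-I gene, DDX58, had been knocked out (KO). The 21 libraries form 7 groups of 3. The WT groups are untreated and given 3p-RNA. Of the KO groups, 4 are untreated, given 3p-RNA, given interferon (IFN) for 4 h, and given IFN for 18 h. In the last KO group cells were given IFN for 18 h and also 3p-RNA, with IFN started first. 3p-RNA is RNA with a triphosphate at its 5' end, the ligand of the cytosolic sensor RIG-I, and was transfected at 160 nM for 6 h. The interferon was IFN-α2a at 1000 U/ml. No group received the transfection reagent alone or a control RNA, and no WT group received IFN.

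Total counts were 14400553, 14560746 and 13285467 in the WT untreated libraries and 15334827, 14158392 and 13482286 in WT with 3p-RNA. They were 24808344, 13270329 and 14957205 in KO untreated, and 14528522, 14056324 and 14751856 in KO with 3p-RNA. KO libraries with IFN for 4 h had 13041852, 13517602 and 13249160 counts, and those with IFN for 18 h had 13407172, 14017176 and 13153172. The libraries with IFN for 18 h and 3p-RNA had 11822568, 12481870 and 11841373. Levels below are CPM (counts scaled to a fixed library total) scaled by TMM factors, as mean ± SD with n = 3 libraries per group. Changes are log2 fold changes with their standard error (SE) and an adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The p-values measure only the spread between these samples, since the labels do not say whether replicates were separate cultures. A level of 0 is bounded by 3 counts per library. Because the reads carry no molecular identifiers, such bounds and the intervals of ratios cover counting error only. The tests, the gene lists and the rule for which genes are named were fixed before the data were examined, apart from what is said to be chosen later.

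The targeted gene, DDX58 (ENSG00000107201, GRCh38 chromosome 9, 32455705 to 32526324), had transcripts in every library of both genotypes. Its level was 14.4 ± 1.23 CPM in WT untreated, 2552 ± 90.0 in WT with 3p-RNA, 21.7 ± 3.57 in KO untreated and 22.6 ± 0.867 in KO with 3p-RNA. It was 1243 ± 26.4 CPM in KO with IFN for 4 h, 226 ± 8.07 at 18 h, and 196 ± 4.09 at 18 h with 3p-RNA. Gene-level counts include reads from outside an edited site, so these levels are no check of the knockout protein.

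**Figure D1:**
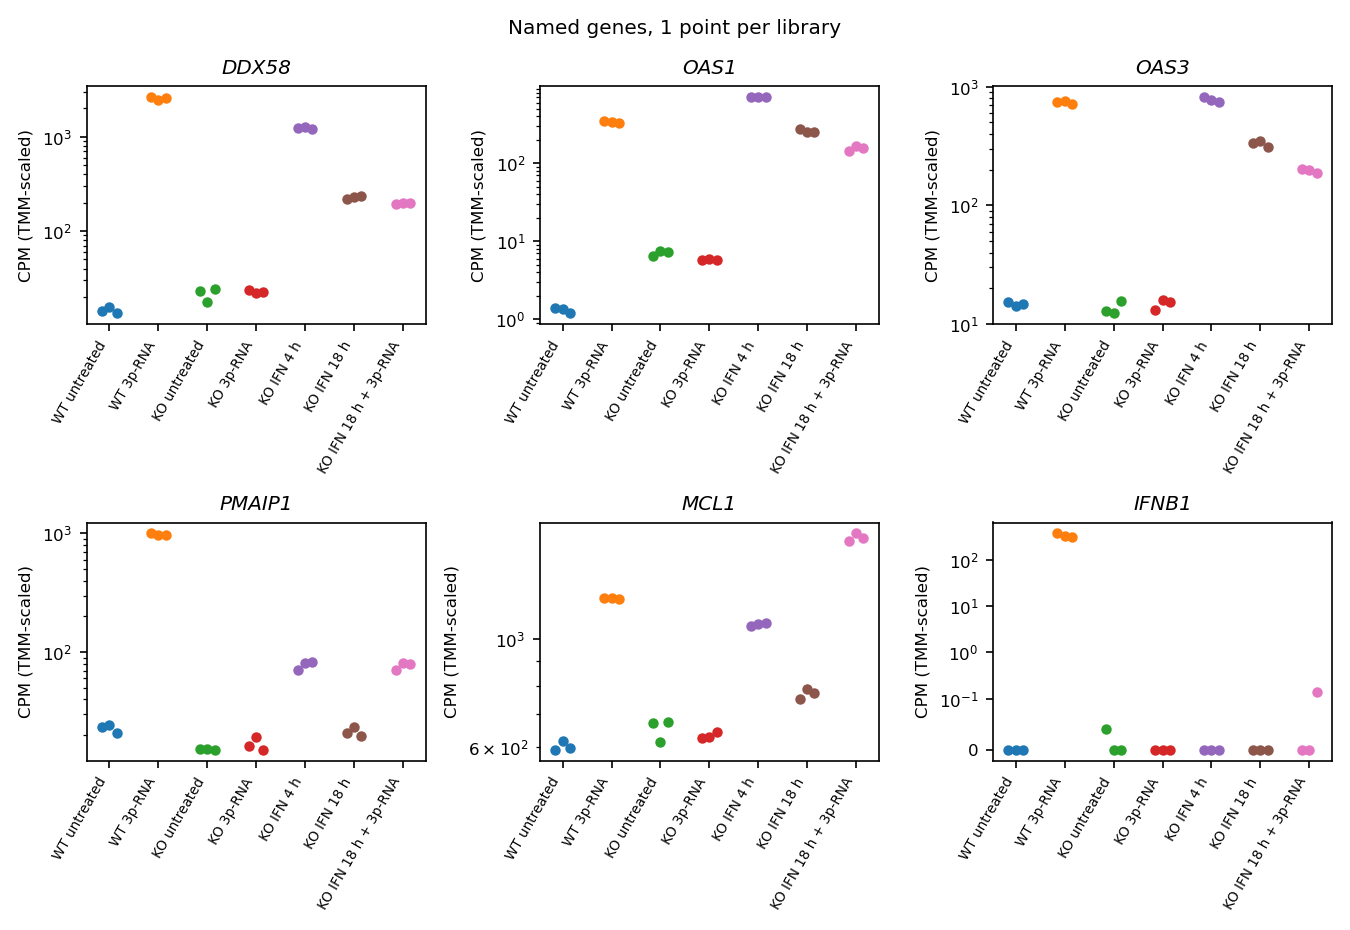
Levels of 6 genes in each of the 21 libraries, 1 point per library, in CPM on a logarithmic axis (for IFNB1 linear below 0.1 CPM). OAS1 had a mean of 1.31 CPM in WT untreated and 338 in WT with 3p-RNA, but 7.13 in KO untreated and 5.83 in KO with 3p-RNA.

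The comparison of WT cells with and without 3p-RNA asked what the RIG-I ligand does to the transcripts of cells that have RIG-I. Interferon and chemokine transcripts came from almost nothing. IFNB1 (ENSG00000171855, chromosome 9, 21077105 to 21077963), which encodes interferon beta, had 0 counts in the untreated libraries and 345 ± 30.7 CPM after 3p-RNA, a rise of at least 1639-fold. The type III interferon gene IFNL1 rose from 1 count in the 3 untreated libraries to 398 ± 19.0 CPM, a ratio of 17100 (95% interval 3060 to 674000), and IFNL3 rose at least 293.9-fold from 0. The chemokine gene CXCL10 rose from 6 counts, all in 1 of the untreated libraries, to 1827 CPM. CXCL9, another chemokine gene, and IDO1, which encodes a tryptophan-degrading enzyme, rose at least 352.5-fold and at least 463-fold from 0. The 6 largest falls were of KCNA2 (a potassium channel gene, 35.2 to 5.77 CPM, log2 −2.60), the transcription factor gene SOX2 (18.4 to 3.03, −2.59), SEMA6D (−2.45), RASL12 (−2.41), the Notch ligand gene DLL4 (−2.37) and OSR1 (−2.35).

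The OAS genes, whose enzymes sense double-stranded RNA, rose together in WT cells. OAS1 (ENSG00000089127, chromosome 12, 112906777 to 112933222) rose from 1.31 ± 0.101 to 338 ± 14.7 CPM (log2 8.001, SE 0.0892, edgeR adjusted p 6.2e-24). OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723) rose from 0.871 ± 0.564 to 517 ± 7.47 CPM (log2 9.17). OAS3 (ENSG00000111331, chromosome 12, 112938352 to 112973249) rose from 14.7 ± 0.543 to 741 ± 19.1 CPM (log2 5.65). PMAIP1 (ENSG00000141682, chromosome 18, 59899948 to 59904306), which encodes the pro-apoptotic protein NOXA, rose from 22.8 ± 1.79 to 981 ± 18.6 CPM (log2 5.42). MCL1 (ENSG00000143384, chromosome 1, 150574551 to 150579738), the gene of an anti-apoptotic protein that NOXA binds, rose from 602 to 1215 CPM (log2 1.01). BCL2L1 (ENSG00000171552, chromosome 20, 31664452 to 31723989), the gene of BCL-XL, did not pass the test (log2 0.07, edgeR adjusted p 0.42). DDX58 rose as well (log2 7.47, SE 0.0915, edgeR adjusted p 1.8e-23).

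All 50 interferon-stimulated genes rose in WT cells given 3p-RNA, with a median of 5.76 (5.73 with members without counts set at their bound), IFIT1 at 10.09 and IFIH1 at 9.77 among them. Of 13 OAS and other double-stranded RNA sensor genes 11 rose and 1 fell (median 5.65). Of 16 RIG-I-like receptor signalling genes 13 rose and 1 fell (median 0.60), with TRIM25 at 3.08 and ZC3HAV1 at 3.99. All 23 NF-kB targets rose (median 5.83), as SOD2 did by 5.83 (SE 0.0593) and CXCL8 by 6.78, and 10 of 11 interferons and IRF3-driven chemokines rose (median 12.39, or 10.68 at the bound). All 17 genes of MHC class I antigen presentation rose (median 2.44), with NLRC5 at 5.94 and TAP1 at 4.79, and 8 of 9 lytic cell death genes rose, MLKL by 2.74. Among 22 immediate-early and stress-kinase genes 18 rose (ATF3 by 6.16, KLF4 by 4.07) and none fell, or 1 fell when adjusted over the list alone. Of 21 pro-apoptotic genes 12 rose and 2 fell (median 0.27, BBC3 at 6.51), and of 11 anti-apoptotic genes 6 rose and 3 fell (median 0.45, BIRC3 at 7.70). With correlation between genes estimated, camera's adjusted p was 2.7e-10 for the interferon-stimulated genes, 3.9e-11 for NF-kB targets, 2.6e-07 for the sensors and for the interferons, 8.1e-06 for RIG-I-like receptor signalling and 9.8e-06 for antigen presentation. It was 2.4e-07 for immediate-early, 0.00023 for lytic death, 7.6e-05 for pro-apoptotic and 0.00506 for anti-apoptotic genes.

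Of 22 p53 targets 9 rose and 7 fell in WT cells, with a median of −0.01, a mean of 0.51 and a camera test upward (adjusted p 0.00329, estimated correlation p 0.0189). Of 33 S and G2/M cell cycle genes 20 fell and 1 rose (median −0.24, AURKA −0.73, KIF20A −0.77), or 21 fell when adjusted over the list alone. Their camera adjusted p of 0.00329 became p 0.246 with estimated correlation. The integrated stress response (7 of 16 up, 4 down, or 5 down when adjusted over the list alone, PPP1R15A at 3.86, CHAC1 at −2.00, camera adjusted p 0.0131) became p 0.246, and the dedifferentiated melanoma genes (9 of 15 up, 4 down, camera adjusted p 0.0074) also became p 0.246. No camera call was made for ER chaperones (4 of 15 up, 2 down, XBP1 at 2.11), ribosomal proteins (11 of 39 up, 2 down, but 3 up and 1 down when adjusted over the list alone), mitochondrially encoded mRNAs (1 of 13 up), nuclear-encoded oxidative phosphorylation (5 of 25 up, 2 down) or cholesterol synthesis (4 of 21 up, 8 down, or 9 down when adjusted over the list alone). The same held for glycolysis and hypoxia genes (1 of 16 up, 7 down), the 5 tested pigment-cell genes (1 up, RAB27A at 0.96) and the 12 replication-dependent histone genes (none called). Of the 14 leukocyte markers none was tested, and their summed level lay between 0.32 and 0.64 CPM in every group. Of the epithelial markers KRT18 fell (−0.23), the only tested endothelial marker, VWF (−0.78), fell only when adjusted over the list alone, and of the fibroblast markers PDGFRA fell (151 to 59.6 CPM) and TWIST2 rose (1.27).

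In the edgeR test 6770 of 16044 genes passed an adjusted p of 0.05 in WT cells, 2997 up and 3773 down, and 1670 of them changed at least 2-fold. Scaled by library size alone, the median of all genes moved to −0.203 and the share of rises among the calls went from 44.3% to 25.5%, so the split of rises and falls depends on the scaling.

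The same 3p-RNA in KO cells asked what remains of that response without RIG-I. None of the 50 interferon-stimulated genes passed the test (median −0.01), and the levels of OAS1 (7.13 ± 0.579 against 5.83 ± 0.160 CPM, log2 −0.27, edgeR adjusted p 0.363), OAS3 (log2 0.12), PMAIP1 (15.3 ± 0.175 against 16.8 ± 2.17 CPM, log2 0.14), MCL1 (−0.05), BCL2L1 (0.02) and DDX58 (0.05) did not pass. OAS2 had 6 counts in the untreated libraries and 1 after 3p-RNA, and IFNB1 had 1 and 0. Among the 13 genes that rose were TXNRD1, the gene of a thioredoxin reductase (529 to 720 CPM, log2 0.44, SE 0.0507, edgeR adjusted p 0.000154), GCLM of glutathione synthesis (40.6 to 58.2 CPM, 0.52), the cystine transporter gene SLC7A11 (4.20 to 7.36 CPM, 0.80), OSGIN1 (21.6 to 32.7 CPM, 0.61) and the autophagy receptor gene SQSTM1 (408 to 537 CPM, 0.40). DLX2 (0.54), MAFG (0.29), ANKRD52 (0.30), ZFP36L1 (0.24) and the pseudogene NMRAL2P (1.30) rose too. So did the transcription factor genes NR4A1 (0.246 to 0.988 CPM, 1.96), NR4A3 (0.321 to 0.939 CPM, 1.59) and ATF3 (1.57 to 3.53 CPM, 1.10). Untreated levels of NR4A1 and NR4A3 lay near what 3 counts per library give. Some genes are named here beyond the rule, which asks for at least 5 CPM. The falls included FAM89B (16.4 to 7.95 CPM, −1.03), SMAGP (−0.48), CNN3 (243 to 187 CPM, −0.38), ARL6IP1 (−0.38), RAB5B (−0.30) and the pseudogene PEBP1P2 (−3.23).

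Few listed genes passed in this comparison. Among them were NR4A1 and ATF3 among the immediate-early genes (4 up and 1 down when adjusted over the list alone) and SLC7A11 in the integrated stress response. Adjusted over the list alone, 12 of 13 mitochondrially encoded mRNAs rose (median 0.52). That median was 0.25 without KO untreated replicate 2 and 0.80 without replicate 1. Also adjusted over the list alone, 2 cell cycle genes, 2 glycolysis genes, 1 oxidative phosphorylation gene and 1 gene of the interferons and chemokines fell, and no other list changed its count. The camera test called 5 lists, each lost with estimated correlation. They were the mitochondrial mRNAs up (adjusted p 5.2e-11) and, downward, ribosomal proteins (median −0.14, 9.8e-10), oxidative phosphorylation (−0.10, 8.2e-06), cell cycle genes (−0.06, 0.000231) and antigen presentation (−0.11, 0.0157). With estimated correlation each of these 5 had p 0.436. In the edgeR test 20 of 16044 genes passed, 13 up and 7 down, and 6 changed at least 2-fold. The count was 614 without a filter on low counts, 37 with DESeq2, 15 with limma-voom and 51 after a GC and length correction chosen after the data were examined. With edgeR on the compared groups only it was 0, with 524 genes at an unadjusted p under 0.05. It fell to 10 without KO 3p-RNA replicate 1, 10 without replicate 2 and 11 without replicate 3. With a term for replicate number 16 of the 20 genes were called again in the same direction, and 15 after thinning. Some genes named here therefore lose their call. KO untreated replicate 2 stood apart from its group, with 1.10% mitochondrial counts and deviations that followed GC content across 11149 genes (rho 0.664).

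Whether the response to 3p-RNA differs between genotypes was tested directly as the WT change minus the KO change. The largest positive differences were of CXCL10, IFNL1, IFNB1, CCL5, OASL and IFNL3, at 1827, 398, 345, 403, 1029 and 61.9 CPM in WT with 3p-RNA and at or near 0 in KO with 3p-RNA. Their fitted differences of log2 14.43 to 18.96 rest on groups with almost no counts and are not bounds. OAS1 differed by 8.28, OAS3 by 5.53, DDX58 by 7.42 and PMAIP1 by 5.29 (SE 0.126, edgeR adjusted p 3e-18). MCL1 differed by 1.06 (SE 0.052, edgeR adjusted p 6.5e-13), while BCL2L1 did not (0.05, edgeR adjusted p 0.734). OAS2 reached 517 CPM in WT with 3p-RNA against 1 count in KO with 3p-RNA. The largest negative differences were KCNA2 −2.87, SEMA6D −2.67, BMF −2.64 (a pro-apoptotic gene), SOX2 −2.59, LONRF2 −2.46 and OSR1 −2.46.

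By list, 47 of 50 interferon-stimulated genes were higher in this difference (median 5.90, or 5.83 at the bound, IFIT3 at 10.27), as were 10 of 13 sensor genes (1 lower), 12 of 16 RIG-I-like receptor signalling genes (1 lower), 20 of 23 NF-kB targets (21 when adjusted over the list alone), 17 of 17 antigen presentation genes (median 2.56) and 17 of 22 immediate-early genes (2 lower, JUN at 2.33). Of pro-apoptotic genes 10 of 21 were higher and 2 lower (median 0.43), of lytic death genes 6 of 9 were higher (7 when adjusted over the list alone, NINJ1 at 4.33), and of p53 targets 8 of 22 were higher and 4 lower (FAS at 2.26). The camera calls of these 9 lists held with estimated correlation, at adjusted p values from 1.4e-09 for NF-kB targets to 0.0134 for p53 targets. Calls lost that way were the interferons and chemokines (9 of 11 higher, camera adjusted p 0.0357, estimated p 0.359), anti-apoptotic genes (6 of 11 higher, 2 lower, 0.00015, estimated p 0.0534) and the integrated stress response (7 of 16 higher, 4 lower, 0.0172, estimated p 0.275). Also lost were the cell cycle (14 of 33 lower, 3 higher, but 16 and 5 when adjusted over the list alone, 0.0363, estimated p 0.464), ribosomal proteins (19 of 39 higher, but 30 higher and 1 lower when adjusted over the list alone, 0.0357, estimated p 0.654) and dedifferentiated melanoma genes (9 of 15 higher, 4 lower, 0.0103, estimated p 0.275). Mitochondrial mRNAs (3 of 13 lower, but 10 when adjusted over the list alone), oxidative phosphorylation (9 of 25 higher, but 10 when adjusted over the list alone), ER chaperones (5 of 15 higher, but 8 when adjusted over the list alone, and 2 lower), cholesterol synthesis (4 of 21 higher, 8 lower), glycolysis (2 of 16 higher, 4 lower), histones (none) and pigment-cell genes (1 of 5 higher) had no camera call. The edgeR interaction test called 5535 genes, 2583 positive and 2952 negative, 1602 of them at least 2-fold. With library size alone the median moved to −0.207 and the positive share from 46.7% to 25.3%.

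Untreated KO cells were set against untreated WT cells to give the baseline on which the other comparisons rest. The bradykinin receptor gene BDKRB2 rose from 0.506 to 99.9 CPM (log2 7.58), MGP, of an extracellular matrix protein, from 3.35 to 305 CPM (6.51), and RARRES3 from 0.0955 to 10.7 CPM, followed by TRHDE (5.23), the integrin gene ITGA11 (5.10) and FAXDC2. ARMCX2 (47.3 CPM in WT), CYBA (9.69 CPM, a NADPH oxidase subunit gene) and TINAGL1 (7.39 CPM) had 0 counts in KO cells, falls of at least 257.4-fold, 52.75-fold and 40.22-fold. HMCN1 fell from 103 to 0.312 CPM (−8.29) and ITIH6 from 44.4 to 0.136 CPM (−8.30), and the phosphatase subunit gene PPP2R2C fell from 444 counts to 2, a ratio of 274 (95% interval 75.5 to 2270). OAS1 was higher in KO cells (log2 2.42, SE 0.121, edgeR adjusted p 5.9e-13) and OAS2 lower (0.871 ± 0.564 against 0.115 ± 0.136 CPM, −2.87). The OAS2 difference rests on few counts, 38 in WT with 22 of them in 1 library, and 6 in KO. DDX58 (0.60), MCL1 (0.12) and BCL2L1 (0.22) were higher, PMAIP1 lower (−0.58), and OAS3 (−0.13) did not pass the edgeR test (adjusted p 0.216).

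All 33 cell cycle genes were lower in KO cells (median −0.88, AURKA −1.28, TPX2 −1.07, PLK1 −1.02; camera adjusted p 3e-19, 0.00953 with estimated correlation). Of 12 replication-dependent histone genes 8 were higher and 1 lower (median 2.42, HIST1H2AC 4.00, HIST2H2BE 3.62; camera adjusted p 2.4e-05, 0.00579 estimated), although the library preparation selects poly(A) RNA, which most histone mRNAs lack. Of the interferon-stimulated genes 31 of 50 were higher and 3 lower (median 0.92, TRIM22 3.14, STAT2 1.39; camera adjusted p 8.8e-07, estimated p 0.103), and of antigen presentation genes 16 of 17 were higher and 1 lower (median 0.89, PSMB9 1.87; 4.7e-06, estimated p 0.144). Immediate-early genes (10 of 22 lower, 6 higher, CTGF −2.82, CYR61 −1.54; camera adjusted p 0.0179) lost the call with estimated correlation (p 0.144). The integrated stress response (10 of 16 lower, 4 higher, SLC7A5 −1.26, MTHFD2 −1.39; 0.0141) lost it as well (p 0.28). Without a camera call were the sensors (4 of 13 higher, 4 lower), RIG-I-like receptor signalling (9 of 16 higher, 3 lower), NF-kB targets (11 of 23 lower, 3 higher, CXCL8 3.15), pro-apoptotic (10 of 21 higher, 5 lower, BMF 3.20), anti-apoptotic (6 of 11 lower, 4 higher, BIRC2 −1.16) and lytic death genes (6 of 9 higher, NLRP1 3.20). The same held for p53 targets (14 of 22 higher, 4 lower, CDKN1A 0.88), ER chaperones (3 of 15 higher, 4 lower), ribosomal proteins (20 of 39 lower, 4 higher), mitochondrial mRNAs (4 of 13 lower, 1 higher), oxidative phosphorylation (9 of 25 higher, 4 lower) and cholesterol synthesis (12 of 21 lower, 3 higher, FASN −1.49). It also held for glycolysis (10 of 16 lower, 4 higher, HK2 −1.67), dedifferentiated melanoma genes (8 of 15 higher, 9 when adjusted over the list alone, 4 lower), pigment-cell genes (2 of 5 higher, 2 lower, MITF −0.97) and the 11 interferons and chemokines (none called). Of the tested marker genes KRT8 (1.56), KRT18 (0.65), TWIST2 (0.79), COL1A1 (0.84) and VWF (1.17) were higher, and KRT14 (−2.50) and PDGFRA (−0.33) lower. Between the genotypes 9609 genes differed in edgeR, 4955 higher and 4654 lower, 2659 at least 2-fold. The labels do not say how many KO clones were used, so a clone's own differences and the loss of RIG-I cannot be told apart here.

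**Figure D2:**
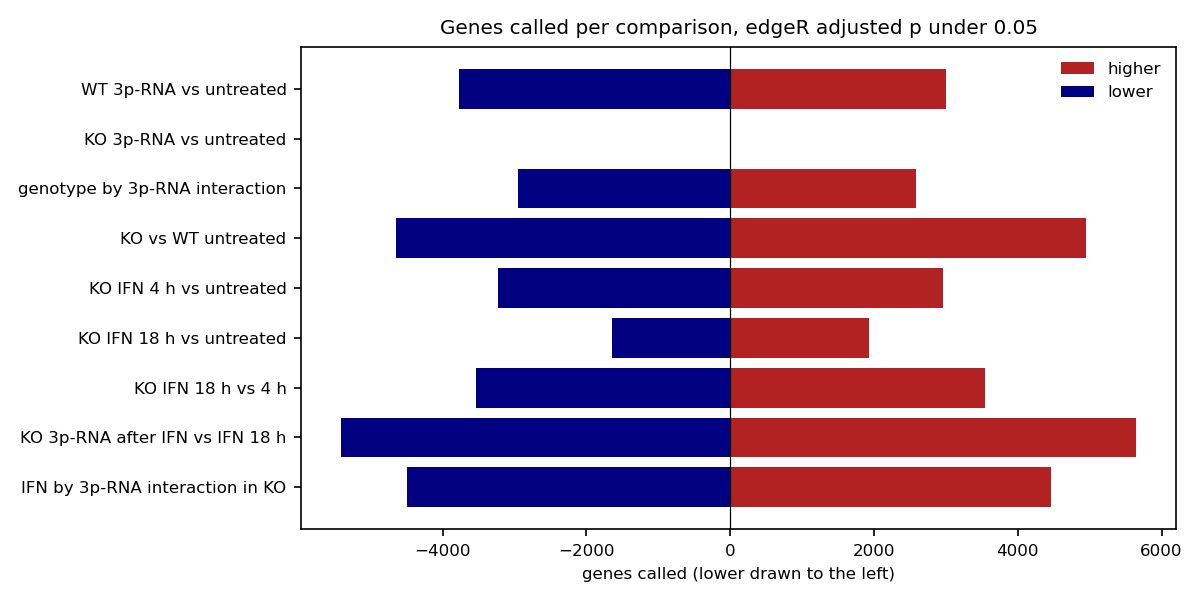
Genes passing an edgeR adjusted p of 0.05 in each of the 9 comparisons, drawn to the right of 0 when higher and to the left when lower. The counts run from 20 for 3p-RNA in KO cells to 11064 for 3p-RNA after IFN.

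IFN for 4 h asked what type I interferon does to cells lacking RIG-I. The death ligand gene TNFSF10 (TRAIL) reached 35.6 CPM from 0 counts, a rise of at least 193.5-fold, and IFI44L, GBP4 and IDO1 rose at least 144.4-fold, 106.8-fold and 101.7-fold from 0. HERC5, of an ISG15 ligase, rose from 1 count to 45.5 CPM, a ratio of 2410 (95% interval 431 to 95100). OAS1 rose from 7.13 ± 0.579 to 711 ± 1.51 CPM (log2 6.65, SE 0.0721, edgeR adjusted p 6e-24), OAS2 from 0.115 ± 0.136 to 292 ± 12.5 CPM (11.22) and OAS3 from 13.5 ± 1.73 to 779 ± 38.8 CPM (5.85). DDX58 (5.83), PMAIP1 (15.3 to 78.0 CPM, 2.35), MCL1 (0.71) and BCL2L1 (0.50) rose, while IFNB1 had 0 counts. The falls included DEPTOR, of an mTOR inhibitor (7.07 to 2.02 CPM, −1.81), KCNA2 (−1.80), N4BP3 (−1.78), CAMKK1 (−1.74) and the Hedgehog transcription factor gene GLI1 (−1.67). FAM156B (−1.83) has a near-identical copy, and the 2 together went from 22.3 ± 2.31 to 14.7 ± 2.17 CPM, so its own change is uncertain.

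Of 50 interferon-stimulated genes 49 rose at 4 h (median 4.98, MX1 8.95, IFIT1 7.52; estimated adjusted p 4.3e-09). Of 13 sensor genes 12 rose and 1 fell (estimated adjusted p 1.5e-08), and of 16 RIG-I-like receptor signalling genes 11 rose and 2 fell (TRIM25 3.82, TLR3 4.11; 1.4e-05). All 17 antigen presentation genes rose (median 2.10, NLRC5 5.63, TAP1 4.64; 1.4e-05), 6 of 9 lytic death genes rose and 1 fell (MLKL 3.35, CASP1 5.86; 0.000614), and 11 of 22 immediate-early genes rose and 2 fell (CYR61 2.49, CTGF 1.95; 0.00904). The interferons and chemokines had 3 rises in 11 (CXCL11 8.03, CXCL10 6.00) with a median of −0.67, or 0.46 at the bound, a mean of 1.33 and a test upward (camera adjusted p 0.00191, estimated p 0.122). Pro-apoptotic genes (10 of 21 up, 6 down, or 8 down when adjusted over the list alone; 0.00347) had an estimated p of 0.0558, and anti-apoptotic genes (7 of 11 up, 1 down, CFLAR among them; 0.00196) an estimated p of 0.0894. Cell cycle genes (19 of 33 down, 2 up; 0.00872) and dedifferentiated melanoma genes (10 of 15 up, 1 down, THBS1 1.07; 0.016) both had an estimated p of 0.31. NF-kB targets (11 of 23 up, 2 down, LIF 0.79), p53 targets (5 of 22 up, 9 down, or 6 and 12 when adjusted over the list alone), the integrated stress response (2 of 16 up, 4 down), ER chaperones (4 of 15 up), ribosomal proteins (1 of 39 up, none when adjusted over the list alone) and mitochondrial mRNAs (8 of 13 up, all 13 when adjusted over the list alone) had no camera call. Nor did oxidative phosphorylation (5 of 25 up, 1 down), histones (5 of 12 up), cholesterol synthesis (3 of 21 up, 8 down, or 4 and 11 when adjusted over the list alone), glycolysis (3 of 16 up, 6 down, HK2 1.42) or the 5 pigment-cell genes (2 up, RAB27A 1.54 with SE 0.0676). In the edgeR test 6185 genes changed, 2958 up and 3227 down, 1320 at least 2-fold, or 3911 genes when only the compared groups were fitted. With library size alone the median moved to −0.197 and the share of rises from 47.8% to 26.1%. The WT response to 3p-RNA and this response, which share no library, had 1657 rises in common against 553 for independent lists, and 1706 falls against 759.

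IFN for 18 h was compared with untreated KO cells for the later state. BST2, which encodes tetherin, rose from 0.113 to 206 CPM (log2 10.96), IFITM1, of an antiviral membrane protein, from 0.218 to 194 CPM (9.81) and IFI27 from 0.211 to 108 CPM (8.74). IFI44L rose at least 28.27-fold from 0, and IFI44 rose from 2 counts to 26.2 CPM, a ratio of 692 (95% interval 191 to 5720). OAS1 stood at 258 ± 14.0 CPM (log2 5.19, SE 0.0698, edgeR adjusted p 6.4e-22), OAS2 at 57.7 ± 5.03 CPM (8.88) and OAS3 at 332 ± 18.6 CPM (4.62). DDX58 (3.37), PMAIP1 (0.48), MCL1 (0.24) and BCL2L1 (0.19, edgeR adjusted p 0.0458) were higher. DEPTOR (−2.22), MGP (305 to 68.6 CPM, −2.15), ITGA9 (−1.94), ZMAT3 (121 to 44.7 CPM), TMOD1 (−1.43) and SUMF1 (40.8 to 17.3 CPM, −1.23) fell.

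Of 50 interferon-stimulated genes 48 were higher at 18 h (MX1 7.17, IFIT1 6.05; estimated adjusted p 2.8e-11), as were 11 of 13 sensor genes (median 2.38; 2e-09) and 16 of 17 antigen presentation genes (median 1.46, B2M 2.27, TAP1 2.22; 6.5e-07). RIG-I-like receptor signalling had 5 of 16 up and 1 down, or 2 down when adjusted over the list alone (estimated adjusted p 0.00833), and histones 7 of 12 up, or 8 when adjusted over the list alone (HIST1H2AC 1.37; 0.00304). Of 39 ribosomal protein genes 34 fell, or 36 when adjusted over the list alone (median −0.36, RPS6 −0.38, RPL4 −0.38), with a camera adjusted p of 2.1e-11 and an estimated p of 0.376. Cell cycle genes (14 of 33 up, 2 down, or 16 and 3 when adjusted over the list alone, RRM2 0.46; 0.00769) had an estimated p of 0.446. No camera call was made for lytic death (5 of 9 up, 1 down, CASP1 2.82), pro-apoptotic (5 of 21 up), anti-apoptotic (3 of 11 up), NF-kB (1 of 23 up, 3 down, CXCL8 −0.71), interferon and chemokine (1 of 11 up, CXCL11 2.53), p53 (5 of 22 up, 3 down, or 4 down when adjusted over the list alone) or immediate-early genes (3 of 22 up, 3 down, EGR1 −0.61). Nor was there one for the integrated stress response (4 of 16 up), ER chaperones (3 of 15 up, 3 down), mitochondrial mRNAs (1 of 13 down), oxidative phosphorylation (2 of 25 up, 1 down, or 1 up and 0 down when adjusted over the list alone), cholesterol synthesis (2 of 21 up, 5 down, or 3 up when adjusted over the list alone), glycolysis (5 of 16 up, 1 down, or 3 down when adjusted over the list alone, BNIP3 0.62), pigment-cell (2 of 5 up, 1 down) or dedifferentiated melanoma genes (5 of 15 up, or 6 when adjusted over the list alone, 2 down). At 18 h 3585 genes differed in edgeR, 1936 up and 1649 down, 351 at least 2-fold, or 1044 genes when only the compared groups were fitted. The WT response to 3p-RNA shared 758 rises (362 for independent lists) and 521 falls (388) with this one.

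KO cells with IFN for 18 h were compared directly with those with IFN for 4 h. The untreated KO group has no stated time, so effects of IFN and of time in culture cannot be told apart. GBP4 went from 19.6 CPM to 0, at least 87.44-fold, and TNFSF10 from 35.6 CPM to 1 count, a ratio of 1430 (95% interval 256 to 56400). IDO1, CXCL9, ZBP1 and GBP5 fell by ratios of 375 (103 to 3100), 317 (56.4 to 12600), 167 (45.8 to 1380) and 122 (33.4 to 1010). DDX58 (−2.46), OAS1 (711 ± 1.51 to 258 ± 14.0 CPM, −1.46, SE 0.0533, edgeR adjusted p 5.5e-15), OAS2 (−2.34), OAS3 (−1.23), PMAIP1 (−1.87), MCL1 (−0.48) and BCL2L1 (−0.31) fell too. IFI27, a late interferon-stimulated gene, rose from 25.3 to 108 CPM (2.10), as did GLI1 (1.95), PALM3, the lipid transporter gene MFSD2A (1.82), LHX6 (1.82) and DHRS2 (84.2 to 293 CPM, 1.80).

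Of 50 interferon-stimulated genes 43 fell and 6 rose between the times (median −1.75, or −1.60 at the bound, IFIT2 −4.50, IFIH1 −3.32; estimated adjusted p 8.4e-07). Sensors (11 of 13 down, 1 up, OASL −4.55; 3.3e-05), RIG-I-like receptor signalling (11 of 16 down, 1 up, TRIM25 −2.30; 3.3e-05), lytic death genes (7 of 9 down, MLKL −2.63; 0.000155), immediate-early genes (10 of 22 down, 11 when adjusted over the list alone, 3 up, CYR61 −2.40; 0.000798) and antigen presentation (11 of 17 down, 4 up, NLRC5 −3.57; 0.0407) held their camera calls with estimated correlation. Pro-apoptotic genes (9 of 21 down, 5 up) had a median of 0.11, a mean of −0.59 and a test downward (estimated adjusted p 0.0407). Cell cycle genes rose in 26 of 33 cases, 27 when adjusted over the list alone, and fell in 1 (median 0.40, CDC6 0.87, RRM2 0.82; camera adjusted p 3.1e-07, estimated p 0.0616). Ribosomal proteins fell in 34 of 39 cases, 36 when adjusted over the list alone (median −0.36; 0.000157, estimated p 0.411). The interferons and chemokines had 3 falls in 11, a median of 0 (−0.17 at the bound) and a mean of −1.69 (0.000391, estimated p 0.0996). NF-kB targets (9 of 23 down, 10 when adjusted over the list alone, 1 up; 0.0254, estimated p 0.0516) and anti-apoptotic genes (6 of 11 down, 7 when adjusted over the list alone, 2 up; 0.00596, estimated p 0.127) lost their calls. So did dedifferentiated melanoma genes (10 of 15 down, 3 up; 0.0111, estimated p 0.269) and glycolysis (8 of 16 up, 2 down, SLC2A1 1.17; 0.0254, estimated p 0.187). There was no camera call for p53 targets (10 of 22 up, 6 down), the integrated stress response (7 of 16 up, 2 down), ER chaperones (5 of 15 down), mitochondrial mRNAs (7 of 13 down, MT-CO3 −1.07), oxidative phosphorylation (8 of 25 down, 2 up), histones (4 of 12 up, 1 down), cholesterol synthesis (8 of 21 up, 3 down, STARD4 −2.14) or pigment-cell genes (1 of 5 up, 1 down). Between the times 7075 genes differed in edgeR, 3546 up and 3529 down, 1257 at least 2-fold. With library size alone the median moved to 0.144 and the share of rises from 50.1% to 68.8%.

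Whether 3p-RNA acts on KO cells that had received IFN was tested in cells with IFN for 18 h. The stated times do not settle whether total time with IFN was equal in these 2 groups. An effect of IFN time therefore cannot be told apart from that of 3p-RNA here. Immediate-early genes rose far above their levels with IFN alone. EGR1, a transcription factor gene, rose from 91.5 to 3318 CPM (log2 5.18, SE 0.0517, edgeR adjusted p 3.5e-24), FOS from 3.23 to 189 CPM (5.86, SE 0.103, edgeR adjusted p 3.7e-20) and ARC from 0.581 to 24.0 CPM (5.36). C11orf96 (0.302 to 20.6 CPM, 6.07), ARRDC4 (1.72 to 60.9 CPM, 5.14) and LURAP1L (2.16 to 70.1 CPM, 5.01) rose likewise. HSP90B1, of an ER chaperone, fell from 2216 ± 46.3 to 457 ± 27.1 CPM (−2.28, SE 0.0576, edgeR adjusted p 6.8e-18), as did HLA-DRA (5.39 to 1.05 CPM, −2.35) and RPL39 (146 ± 59.6 to 27.4 ± 22.0 CPM, −2.42). U2AF1 (−6.33), SMN2 (−4.92) and SLX1B (−2.47) share reads with near-identical copies and are uncertain. With their copies added they went from 84.8 ± 44.2 to 60.5 ± 33.4, from 59.4 ± 19.4 to 23.7 ± 2.35 and from 5.90 ± 1.01 to 1.06 ± 0.306 CPM. PMAIP1 rose from 21.3 ± 1.87 to 76.8 ± 5.74 CPM (1.85) and MCL1 from 772 to 1620 CPM (1.07). In the same groups GAPDH went from 7644 to 2949 CPM, EEF1A1 from 2948 to 1132 CPM and ACTB from 5100 to 2566 CPM. As CPM are shares of a library, rises here do not show that a transcript gained in amount per cell. OAS1 (258 ± 14.0 to 157 ± 10.1 CPM, −0.72), OAS2 (−0.74), OAS3 (332 ± 18.6 to 196 ± 6.86 CPM, −0.76) and DDX58 (−0.21) fell, BCL2L1 did not pass (0.02, edgeR adjusted p 0.846), and IFNB1 had 2 counts against 0. Scaled by library size alone, DDX58 had a value of 0.08, so its direction depends on the scaling. On that scale BCL2L1 stood at 29.2 ± 0.743 CPM with IFN and 36.1 ± 2.2 CPM with IFN and 3p-RNA, so its flat result depends on it as well.

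Of 22 immediate-early and stress-kinase genes 21 rose and 1 fell after IFN and 3p-RNA (JUN 3.04; estimated adjusted p 4.9e-08). The integrated stress response had 12 of 16 up and 2 down (median 1.06, DDIT3 4.31, PPP1R15A 3.47; 0.0092) and NF-kB targets 16 of 23 up (median 1.67, or 1.43 at the bound, LIF 2.40, NFKBIA 2.46; 0.000621). ER chaperones fell in 12 of 15 cases and rose in 1 (median −1.24, PDIA6 −2.02; 3.8e-05), antigen presentation genes in 16 of 17 with 1 rise (median −1.13, B2M −1.29, ERAP2 −2.21; 0.0168) and glycolysis genes in 10 of 16 with 5 rises (median −0.49, LDHA −2.00, P4HA1 −1.92; 0.0168). Cell cycle genes fell in 28 of 33 cases and rose in 1 (median −0.79, MCM6 −1.38; 0.0487), and histone genes rose in 10 of 12 and fell in 1 (median 1.27, HIST1H4H 2.25; 0.0168). All 25 oxidative phosphorylation genes fell (median −0.78, ATP5F1B −1.25; camera adjusted p 1.6e-09, estimated p 0.0512), and of ribosomal proteins 36 of 39 fell and 1 rose (median −0.80, RPL3 −1.12; 8.5e-10, estimated p 0.237). Dedifferentiated melanoma genes (10 of 15 down, 5 up, TGFBI −1.91, VIM −1.35; 0.000142, estimated p 0.106), p53 targets (11 of 22 up, 6 down, SESN2 2.29; 0.0213, estimated p 0.0616) and interferon-stimulated genes (22 of 50 down, 11 up, median −0.14, BST2 −1.58; 0.0428, estimated p 0.394) lost their calls. Mitochondrial mRNAs rose in 11 of 13 cases (median 0.60, MT-ND3 0.49) without a camera call. Sensors (3 of 13 up, 6 down), RIG-I-like receptor signalling (8 of 16 up, 5 down, ZC3HAV1 1.60), the interferons and chemokines (1 of 11 up, IFNE 3.07), pro-apoptotic (11 of 21 up, 4 down, BCL2L11 1.93, BBC3 2.11), anti-apoptotic (6 of 11 up, 2 down, BIRC3 3.63), lytic death (1 of 9 up, 6 down), cholesterol synthesis (6 of 21 up, 12 down, INSIG1 2.16) and pigment-cell genes (1 of 5 up, 2 down) had none either. In the edgeR test 11064 genes changed, 5649 up and 5415 down, 3797 at least 2-fold. The TMM factors of these libraries were 1.20 to 1.23, and with library size alone the median moved to 0.312 and the share of rises from 51.1% to 68.1%. The 100 highest genes held a share of 20.05% of the counts with IFN alone and 15.3% ± 0.322 (SD, n = 3) with 3p-RNA, and mitochondrial counts went from 1.29% to 2.62%.

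**Figure D3:**
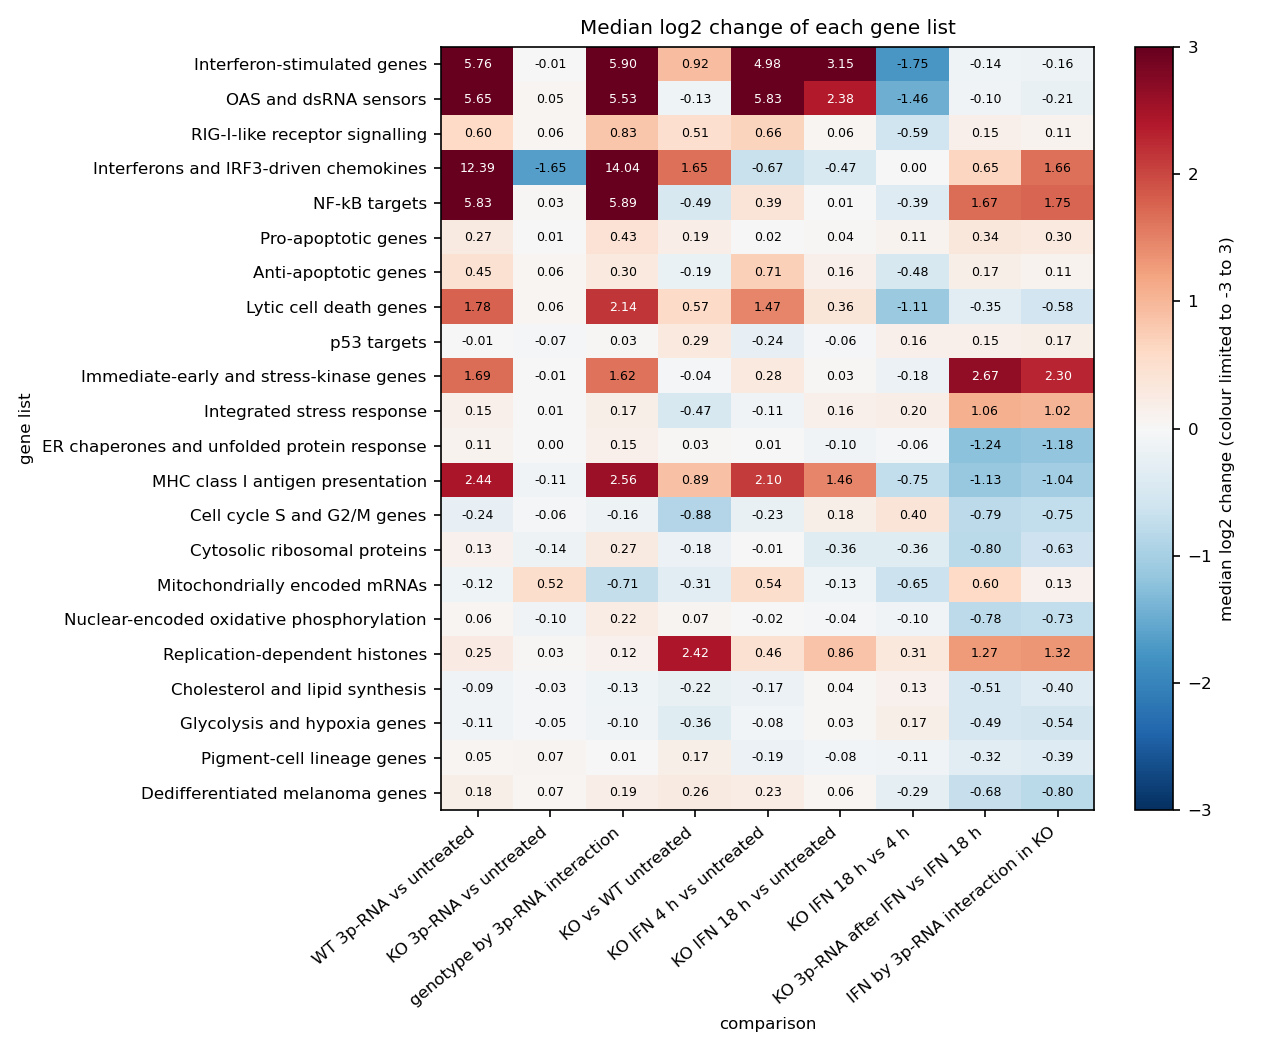
Median log2 change of the tested members of each gene list in the 9 comparisons, with colour limited to −3 to 3. Immediate-early genes had a median of 1.69 after 3p-RNA in WT cells, −0.01 in KO cells and 2.30 in the IFN interaction in KO cells.

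Whether the response of KO cells to 3p-RNA differs with IFN was tested as the change after IFN minus the change without it. As in the comparison above, an effect of total time with IFN cannot be told apart here. The largest positive differences were FOS 5.44, C11orf96, HIST2H3C 5.24, EGR1 5.10 (SE 0.0658, edgeR adjusted p 5.6e-22), ARC 4.81 and the cytokine gene IL11 (6.84 to 197 CPM with IFN, 4.81). HIST2H3C has identical copies, whose sum went from 1.36 ± 0.660 to 11.3 ± 2.21 CPM with IFN. Without IFN the sum went from 1.29 ± 0.436 to 0.819 ± 0.345 CPM. The largest negative differences were HLA-DRA −2.61, NOMO3 −2.42 (its copies summed 457 ± 81.5 and 155 ± 29.1 CPM with IFN, 432 ± 69.0 and 484 ± 14.2 without), HSP90B1 −2.36, NEGR1 −2.33, the peptidase gene ERAP2 (302 to 65.3 CPM with IFN) and PGAM1 −2.29. PMAIP1 differed by 1.71 (SE 0.126, edgeR adjusted p 3.8e-10) and MCL1 by 1.12 (SE 0.052, edgeR adjusted p 3.5e-13). OAS1 (−0.45), OAS3 (−0.88) and DDX58 (−0.26, edgeR adjusted p 0.0464) differed downward, while OAS2 (1.21) and BCL2L1 (−0.01) did not pass the edgeR test (adjusted p 0.416 and 0.949). With library size alone DDX58 was at 0.02 and BCL2L1 at 0.26. BCL2L1 then passed the edgeR test (adjusted p 0.0224).

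Immediate-early genes were higher in this difference in 20 of 22 cases (JUN 3.14; estimated adjusted p 4.7e-08), the integrated stress response in 10 of 16 with 2 lower (median 1.02, DDIT3 4.10; 0.00675), NF-kB targets in 13 of 23 with 1 lower (median 1.75, or 0.95 at the bound, TRAF1 1.77; 0.00141), p53 targets in 8 of 22 with 5 lower (GADD45A 1.62; 0.0365) and histones in 10 of 12 (median 1.32; 0.029). ER chaperones were lower in 12 of 15 with 1 higher (median −1.18, HSPA5 −1.57; 4.3e-05), antigen presentation in 15 of 17 with 1 higher (TAPBP −1.17; 0.029) and glycolysis in 10 of 16 with 4 higher (0.0283). Oxidative phosphorylation (23 of 25 lower, 24 when adjusted over the list alone; camera adjusted p 7.1e-08, estimated p 0.0713), cell cycle genes (28 of 33 lower, 2 higher, or 3 when adjusted over the list alone; 3.9e-07, estimated p 0.0695), ribosomal proteins (35 of 39 lower, 1 higher; 2.3e-07, estimated p 0.338) and dedifferentiated melanoma genes (9 of 15 lower, 10 when adjusted over the list alone, 2 higher; 1.5e-05, estimated p 0.0695) lost their calls. No camera call was made for interferon-stimulated genes (7 of 50 higher, 14 lower, or 13 when adjusted over the list alone), sensors (3 of 13 higher, 5 lower), RIG-I-like receptor signalling (4 of 16 higher, 4 lower), the interferons and chemokines (2 of 11 higher, 1 when adjusted over the list alone), pro-apoptotic (7 of 21 higher, 3 lower, BCL2L11 1.76) or anti-apoptotic genes (5 of 11 higher, 1 lower). Nor was one made for lytic death (4 of 9 lower), mitochondrial mRNAs (1 of 13 higher), cholesterol synthesis (3 of 21 higher, 11 lower) or pigment-cell genes (1 of 5 higher, 2 lower). The IFN interaction covered 8969 genes in edgeR, 4469 positive and 4500 negative, 3175 at least 2-fold. With library size alone the median moved to 0.291 and the positive share from 49.8% to 68.5%. In data simulated for this comparison 7.93% of the calls were false, above the nominal 5%.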

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

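The results of this part are those in which the difference between 2 responses was itself tested and passed, with a weighing of the plain contrast of 3p-RNA after IFN at the end; the splits of the samples, the test of cytosolic mRNA loss and the thinning and GC corrections were run after the count of genes was known, although what depth or GC bias would show after IFN had been written down earlier.

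The response to 3p-RNA differed between WT and KO cells for 5535 genes. In WT with 3p-RNA the genes CXCL10, IFNL1, IFNB1, CCL5, OASL, IFNL3 and OAS2 reached 1827, 398, 345, 403, 1029, 61.9 and 517 CPM, against at most 19 counts summed over a KO group of this comparison. The differences in log2 were 7.42 for DDX58, 8.28 for OAS1, 5.53 for OAS3, 5.29 for PMAIP1 and 1.06 for MCL1. They were −2.87 for KCNA2, −2.67 for SEMA6D, −2.64 for BMF, −2.59 for SOX2, −2.46 for LONRF2 and −2.46 for OSR1. List medians were 5.90 for interferon-stimulated genes, 5.53 for the sensors, 0.83 for RIG-I-like receptor signalling, 14.04 for the interferons and chemokines (9.34 at the bound), 5.89 for NF-kB targets and 2.56 for antigen presentation. They were 0.43 for pro-apoptotic, 0.30 for anti-apoptotic and 2.14 for lytic death genes, 0.0290 for p53 targets, 1.62 for immediate-early genes and 0.17 for the integrated stress response. They were −0.16 (table value −0.155) for the cell cycle, 0.27 for ribosomal proteins and 0.19 for dedifferentiated melanoma genes. With estimated correlation 6 of these 15 list calls were lost: interferons and chemokines (adjusted p 0.359), anti-apoptotic genes (0.0534), integrated stress response (0.275), cell cycle (0.464), ribosomal proteins (0.654) and dedifferentiated melanoma genes (0.275). Of 60 splits of these 12 libraries, 9 called at least as many genes as the 5535 of the real groups, with 7973 the highest. Of the 8 random splits with as many, 7 kept the 3 WT 3p-RNA libraries on the same side, as 15 of 59 random splits did, and the highest of the rest was 5546. Keeping those libraries together was not enough, since other such splits called 0 to 879 genes. The highest split set 3 WT 3p-RNA and 2 WT untreated libraries with 1 KO untreated library. Each split with as many was likewise uneven in genotype and so still holds much of the difference between the genotypes. This points to a structure of the samples, and nothing is concluded from the share of splits. The cause was not tested.

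KO cells with IFN differed between 4 h and 18 h for 7075 genes, against 1 as the highest of the other splits. Of 10 splits 1 reached that count, too few splits for a share under 0.05. In each comparison of 2 groups the other splits mix the real groups. The difference between the groups then adds to the spread, so few calls come from the design, and nothing is concluded from them. Effects of IFN and of time in culture cannot be told apart here. The log2 changes were 2.10 for IFI27, 1.95 for GLI1, 1.85 for PALM3, 1.82 for MFSD2A and for LHX6, and 1.80 for DHRS2. GBP4, TNFSF10, IDO1, CXCL9, ZBP1 and GBP5 had 19.6, 35.6, 18.7, 7.89, 8.33 and 6.07 CPM at 4 h and 0 to 2 counts at 18 h. DDX58 was at −2.46, OAS1 −1.46, OAS2 −2.34, OAS3 −1.23, PMAIP1 −1.87, MCL1 −0.48 and BCL2L1 −0.31. List medians were −1.75 for interferon-stimulated genes, −1.46 for the sensors, −0.59 for RIG-I-like receptor signalling, 0 for the interferons and chemokines, −0.39 for NF-kB targets and 0.11 for pro-apoptotic genes. They were −0.48 for anti-apoptotic and −1.11 for lytic death genes, −0.18 for immediate-early genes, −0.75 for antigen presentation, 0.40 for the cell cycle, −0.36 for ribosomal proteins, 0.17 for glycolysis and −0.29 for dedifferentiated melanoma genes. With estimated correlation 7 of these 14 list calls were lost: interferons and chemokines (adjusted p 0.0996), NF-kB targets (0.0516), anti-apoptotic genes (0.127), cell cycle (0.0616), ribosomal proteins (0.411), glycolysis (0.187) and dedifferentiated melanoma genes (0.269). The cause was not tested.

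The response of KO cells to 3p-RNA differed between cells with and without IFN for 8969 genes. Effects of total time with IFN and of the transfection itself cannot be told apart from it here. Of 60 splits 1 reached the count of 8969, the real one, with 8426 the highest of the others. That other split kept the 3 libraries with IFN and 3p-RNA on the same side and so still holds their response. This points to a structure of the samples, and nothing is concluded from the share of splits. The log2 differences were 5.44 for FOS, 5.34 for C11orf96, 5.24 for HIST2H3C, 5.10 for EGR1, 4.81 for ARC and for IL11, 1.71 for PMAIP1 and 1.12 for MCL1. They were −2.61 for HLA-DRA, −2.42 for NOMO3, −2.36 for HSP90B1, −2.33 for NEGR1, −2.32 for ERAP2, −2.29 for PGAM1, −0.26 for DDX58, −0.45 for OAS1 and −0.88 for OAS3. HIST2H3C and NOMO3 have near-identical copies, which makes their values uncertain. Their summed copies went from 1.36 to 11.3 and from 457 to 155 CPM with IFN, and from 1.29 to 0.819 and from 432 to 484 CPM without it. List medians were 1.75 for NF-kB targets (0.95 at the bound), 0.17 for p53 targets, 2.30 for immediate-early genes, 1.02 for the integrated stress response and 1.32 for histones. They were −1.18 for ER chaperones, −1.04 for antigen presentation, −0.75 for the cell cycle, −0.63 for ribosomal proteins, −0.73 for oxidative phosphorylation, −0.54 for glycolysis and −0.80 for dedifferentiated melanoma genes. Lost with estimated correlation were 4 of these 12 list calls: cell cycle (adjusted p 0.0695), ribosomal proteins (0.338), oxidative phosphorylation (0.0713) and dedifferentiated melanoma genes (0.0695).

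After IFN, 3p-RNA changed 11064 genes in cells without RIG-I, against 0 as the highest of the other splits, and 1 of 10 splits reached that count. The splits are too few for a share under 0.05, and the others mix the real groups, so nothing is concluded from them. GC or length bias is argued against as the whole cause, since 92.7% of the calls were kept after the correction. Thinning kept 97.2%, but the compared libraries held only 11822568 to 14017176 counts. Thinning to 11822568 could therefore hardly have removed most calls, and it does not decide on depth. A loss of cytosolic mRNA that spares mitochondrial and nuclear RNA stays open: the median of 13 mitochondrial mRNAs (0.598) lay 0.578 above that of all genes (0.0202) and that of 8 nuclear-retained RNAs (0.936) more, but the rise of the mitochondrial share (1.29% to 2.62%) was known and the nuclear list was written after values were seen, so this restates what prompted it. The mitochondrial set had no camera call here (camera adjusted p 0.135, estimated p 0.658). It was called by camera without a filter on low counts, and by fry, which does not set a list against the other genes. Without IFN, where 20 genes changed, its median was 0.52 (0.25 without KO untreated replicate 2). There camera at the preset correlation called it and fry did not. In the IFN interaction its median was 0.13 (1 of 13 called, estimated p 0.848), and 0.42 without that replicate. Poly(A) selection, cell death and a difference in total time with IFN were not tested.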

How the results depend on the processing

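Thinning, the GC and length correction and the closer look at KO untreated replicate 2 were chosen after the results were seen. With a 2-fold threshold the counts were 1670 (WT 3p-RNA), 6 (KO 3p-RNA), 1602 (genotype interaction), 2659 (KO against WT), 1320 (IFN 4 h), 351 (IFN 18 h), 1257 (18 h against 4 h), 3797 (3p-RNA after IFN) and 3175 (IFN interaction). The 20 genes of KO 3p-RNA became 614 without a filter on low counts, 37 with DESeq2, 15 with limma-voom, 51 with the GC and length correction and 0 with edgeR on the compared groups only, which gave 524 at an unadjusted p under 0.05 (1963 with all libraries). Leaving out single libraries gave 10 to 25, with 10 without KO 3p-RNA replicate 1, 10 without replicate 2 and 11 without replicate 3. Fitting only the compared groups gave 3911 genes for IFN 4 h and 1044 for IFN 18 h. In the order above without KO 3p-RNA, leaving out single libraries gave 5985 to 6227, 4842 to 5900, 8888 to 9614, 5326 to 6526, 2629 to 3997, 6299 to 6443, 10494 to 10642 and 8555 to 9549. With library size only, signs reversed for HSPA5 at IFN 4 h (−0.0284), DDX58 (0.0835) with 3p-RNA after IFN, and DDX58 (0.0179) and BCL2L1 (0.26) in the IFN interaction. With estimated correlation 41 of 97 list calls were lost. With fry 5 were lost and 56 list results without a camera call gained one. Without a filter on low counts 4 were lost and 32 gained. A list without a camera call can therefore still hold changed genes. With replicate block the counts were 6653, 17, 5398, 9543, 6108, 3425, 7000, 10986 and 8891, and no list call changed. Of the genes followed across the settings 2 lost their call. For KO 3p-RNA 16 of the 20 genes were called again in the same direction. More of the genes named in the text for KO 3p-RNA therefore lost their call. No pairing by replicate number was seen: 1 of 21 correlations of same-numbered libraries in compared groups exceeded 0.1, over all groups 11 of 63 did (highest 0.285) against 23 of 126 of differently numbered ones, and 3 of 21 libraries lay closest to their own number.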

Other observations

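The counts of genes called were planned, while the tests by RNA class and of the NRF2 list, the thinning, the GC and length correction, the look at KO untreated replicate 2 and the splits were chosen after the results were seen. Genes of zinc finger transcription factors named ZNF rose as a class when KO cells with IFN received 3p-RNA, 312 of 362 up and 9 down (quartiles 0.60 and 1.35, median 1.01 after the GC and length correction; camera adjusted p 7.4e-18, 2.8e-05 with estimated correlation). Long intergenic RNA genes rose in 331 of 594 cases and fell in 23 (median 0.97; 9.8e-06, 8.9e-05 estimated), and antisense RNA genes in 391 of 689 with 25 falls (median 0.92), although the strand setting of the counting is not given, so that these can hold reads of the genes opposite. Processed pseudogenes fell in 517 of 1143 cases and rose in 66 (median −0.66), but −0.15 after the correction. In WT cells given 3p-RNA, ZNF genes had a median of −0.16 and long intergenic RNA genes −0.31 (camera adjusted p 0.295 for both). Of 8 RNAs listed as nuclear-retained, NEAT1 rose from 122 to 575 CPM (log2 2.24) and MALAT1 from 55.4 to 107 CPM (0.94). KCNQ1OT1 (1.74), MEG3 (0.94) and PVT1 (0.93) rose too, OIP5-AS1 fell (−0.23), and FTX (0.24) and JPX (0.17) were not called. Since CPM are shares of a library, these rises and those of the classes above do not show more RNA per cell. The cause was not tested.

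The 20 genes that changed in KO cells given 3p-RNA hold 6 of 25 tested targets of NRF2, the transcription factor of the oxidative stress response. Neither KO untreated replicate 2, without which 80% of them (16 of 20) were called again, exactly at the bound set for it, nor GC and length bias (100% called again) is favoured as the whole cause. An NRF2 response may take part, since the 19 other targets, 14 of them positive with a median of 0.07, were higher as a set (camera adjusted p 0.000181), but not with estimated correlation (p 0.0834), and after IFN the same 19 were lower as a set (median −0.69, 3 up, 14 down, 6.95e-05; 0.0834 estimated). Without 4 of these 19, looked at before the list was written, the p was 0.0215, and 0.243 with estimated correlation, so this stays open. The transfection itself is untested, as no group received it without 3p-RNA. The splits are too few (1 of 10 reached the real 20, highest other 2), and the others mix the real groups.

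KO and WT cells differed without treatment in 9609 genes, against 0 as the highest of the other splits (1 of 10 reached the real count, too few splits). The other splits mix the genotypes, so nothing is concluded from the 0. GC or length bias is argued against as the whole cause, with 85.9% of the calls kept after the correction. Thinning to 11822568 counts kept 94.8%, but it cut only KO untreated replicate 1 strongly (24808344 counts). A loss of most calls was hardly possible there, so thinning does not decide on depth. The loss of RIG-I and differences between clones may each contribute, and the design holds nothing that separates them, so both stay untested.

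For the remaining comparisons the real counts of genes were 6770 for WT 3p-RNA (highest other split 0), 6185 for IFN at 4 h (highest other 2) and 3585 for IFN at 18 h (highest other 894). In each, 1 of 10 splits reached the real count, too few splits for a share under 0.05, and the others mix the real groups. The split with 894 set KO untreated replicates 1 and 3 with IFN 18 h replicate 2. Deviations of these libraries from their group rose with transcript length across genes (rho 0.477, 0.469 and 0.397). Those of KO untreated replicate 2 and IFN 18 h replicates 1 and 3 fell with it (rho −0.536, −0.24 and −0.197). Whether length bias made these calls was not tested.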
